A study of Hordeum vulgare with 32 samples.

How the data were processed

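Total RNA of barley (Hordeum vulgare) main shoot apices was profiled in 32 libraries from 5 lines at 2 Waddington stages, W3.5 and W5.5. Waddington stages describe how far the inflorescence meristem and its floral organs have developed. The stage names are those of the sample labels; the series text and the headers of the deposited table give the later stage as W5.0. Plants were grown in 16 h of light at 22 °C and 8 h of dark at 18 °C, and apices were taken when 6 to 8 h of light remained, per the labels' protocols. Bowman, a 2-rowed cultivar and the recurrent parent of the other lines, had 4 libraries per stage. The introgression lines int-a.1 (stock GSHO 2055), vrs4.k (1986), vrs1 (1907) and int-c.5 (2003) had 3 libraries per group. Each carries an allele of a locus that acts on the fertility of the lateral spikelets. The deposited headers name the int-a.1 columns vrs3(int-a.1).

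The authors deposited 1 table of the whole series with 30174 transcripts. Per the file headers its expression columns are raw counts, but the values are not whole numbers, and each library sums to between 980900 and 987700. They were therefore treated as TPM, a length- and library-scaled abundance, with the unit taken from the values and not from a statement of the authors. The deposited TPM values have 1 decimal in 26 columns, and 1 column (int-c.5 W3.5 replicate 1) holds TPM rounded to whole numbers, which was recorded as a score and used on the same scale as the other deposited columns. The other 5 int-c.5 columns have more decimals, and whether int-c.5 was processed separately is not given in the sources used here. The submitters' processing notes name BWA, Salmon, limma and GATK without versions or roles. The genome build is not given in the sources used here. Per the file headers the table also holds the authors' log2 fold changes of each line against Bowman and their p-values and false discovery rates, which were used only for comparison. How the authors computed these deposited log2 values and p-values is not given in the sources used here.

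Columns of the table name a line and a stage but not a sample, so each column was assigned to its group and the replicate numbers are names only. There were 0 per-sample columns that could not be assigned. TPM keeps no sequencing depth, so the depth of each library is unknown and no interval for counting error is given. A TPM of 0 is described as listed at 0. Gene names come from the best Arabidopsis and rice matches that the table itself gives; none of its identifiers matched the reference gene table used here. Of the 30174 transcripts, 13505 are high-confidence gene models, 15854 are low-confidence models and 815 have no class. An Arabidopsis match is given for 16003 transcripts and a rice match for 18349. A chromosome from 1 to 7 and a PopSeq map position are given for 17249; the table names no unit for the position. Since no genome was used, exons, start and end coordinates are not reported. Near-identical copies can share reads, and low-confidence models can be fragments of one gene.

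All 32 libraries were fitted together in limma 3.58.1 (R 4.3.3; lmFit and eBayes without trend or robust options) on log2(TPM + 1), with 10 line-by-stage groups and no covariate. The planned filter, at least 1 TPM in at least 3 libraries, removed no transcript, so a comparison with no filter was void. A transcript is called where the Benjamini-Hochberg adjusted p is below 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of weakly expressed transcripts. Values after ± are SDs of TPM over n libraries. SE is the standard error of the log2 fold change. The 17 planned comparisons were 8 of a line with Bowman at one stage, 5 of W5.5 with W3.5 within a line, and 4 interactions of line and stage. Averages over both stages, or over the 5 lines, were added after the data were seen, as 5 comparisons.

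The comparisons, the tests, 29 gene lists built from key words in the descriptions of matched genes, most of the alternatives and the rule for naming transcripts were fixed before the data were examined. The naming rule takes, in each line comparison, up to 6 of the highest and 6 of the lowest fold changes among called transcripts whose groups do not overlap and whose match is informative, every member of a list of row-type factors, and up to 2 called members of each other list, to at most about 30. Transcripts named outside this rule are said to be so. Lists were tested with limma's camera at a preset correlation of 0.01 and again with the correlation estimated from the residuals, with adjustment over the 261 list tests. Counts adjusted over a list alone are given beside counts adjusted over all transcripts.

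Calls shared by lines were compared with 100 simulated sets of unchanged lines against the same Bowman libraries, with the count that independent lists give, and with the Bowman libraries split 2 and 2 in each of 6 ways. The share of called transcripts on the chromosome of each line's locus was compared with the other placed transcripts by Fisher's exact test, two-sided, and windows of 50 neighbouring placed transcripts were scanned for the densest calls with 1000 permutations. Other splits of the libraries into groups of the same sizes were refitted, up to 100 per comparison. A simulation of int-a.1 against Bowman at W3.5 changed 200 of 30174 transcripts. The fit found 70% of log2 changes of 1 and 93% of those of 2, and 4.68% of calls were false. Real libraries, where another split gave 624 calls, may have other rates.

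The alternatives were quantile normalization and median centring of the log values, a pseudocount of 0.1, a filter at 5 TPM, a mean-variance trend in the fit, library weights, a fit with only the groups compared, an adjusted p of 0.01, a minimum of 2-fold, the Bowman split, windows of 25 and 100, an estimated correlation for lists, and each library left out in turn. A covariate for the first principal component, leaving out 4 libraries that lie apart from their stage, and the averages over stages or lines, with the alternatives applied to them, were chosen after seeing the data. Summing transcripts to genes was not run, because each gene identifier of the table has 1 transcript. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

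Nothing in the labels says whether replicates came from separate plants or pools of plants, so p-values measure only the spread between these libraries, which may be technical.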

Results

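Transcript abundance was measured by RNA sequencing in the main shoot apex of 5 barley lines at stages W3.5 and W5.5. Bowman, the 2-rowed recurrent parent, was represented by 4 libraries per stage, and the introgression lines int-a.1, vrs4.k, vrs1 and int-c.5 by 3 libraries per group. All 30174 transcripts of the deposited table were tested. Library totals lay between 980900 and 987700 TPM, which reflects the scaling, and sequencing depth is unknown.

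The libraries were spread along a first principal component that held 24.2% of the variance, with a median score of -22.92 at W3.5 and 18.6 at W5.5. The mean log2(TPM + 1) of the lipid transfer list was 4.40 in Bowman W3.5 replicate 1, which scored -56.56, and 3.10 in Bowman W5.5 replicate 2, which scored 56.78. In 4 libraries the score lay past the median of the other stage: Bowman W3.5 replicate 4 (21.71), int-a.1 W3.5 replicate 1 (24.42), vrs4.k W3.5 replicate 2 (52.95) and int-c.5 W5.5 replicate 1 (-29.63). In vrs4.k W3.5 replicate 2 the mean of the MADS-box list was 4.50, above that of all 4 Bowman W5.5 libraries, the highest of which was 4.28. The photosynthesis mean of int-c.5 W5.5 replicate 1 was 4.44, against at most 4.00 in any Bowman library. The libraries correlated at r = 0.917 or more across transcripts within a group, and 14 of 32 correlated best with the mean of their own group. No pair of libraries was identical (0 pairs).

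**Figure D1:**
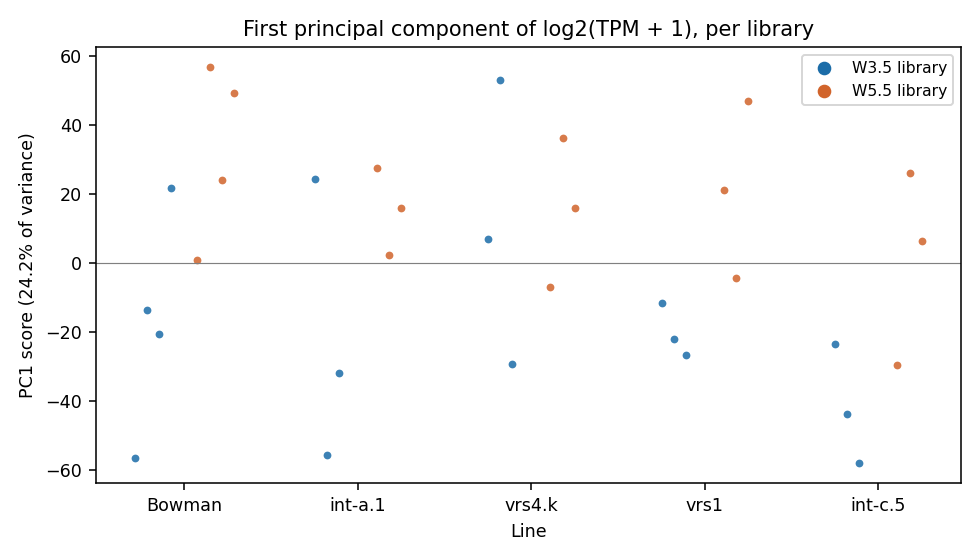
Score of each library on the first principal component of log2(TPM + 1) over 30174 transcripts, by line (horizontal axis) and stage (colour); each point is 1 library. Bowman W3.5 replicate 4, int-a.1 W3.5 replicate 1 and vrs4.k W3.5 replicate 2 lie above 20 among mostly negative W3.5 scores, and int-c.5 W5.5 replicate 1 lies at -29.63.

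The first question was how transcripts picked for the row-type loci behaved in each line. The 4 transcripts, of untested identity, were picked from the table's matches after its values could be seen. AB259783.1 (MLOC_4993.2), HD-Zip homeobox, at position 79.39 of chromosome 2, stands for VRS1. The LOB-domain transcript AK373051 (LBD41 match, chromosome 3, 39.38) stands for VRS4. The TCP transcript MLOC_70116.1 (chromosome 4, 25.85) stands for INT-C, related to the branching repressor TEOSINTE BRANCHED 1. The jmjC-domain transcript MLOC_69611.1 (chromosome 1, 47.52) stands for INT-A. The labels give no lesions, so levels do not check the lines' identity. In the 6 vrs1 libraries the HD-Zip transcript ranged from 4.9 to 30 TPM, against 3.8 to 30.9 in the 8 Bowman libraries, and was not called at either stage. AK373051 ranged from 2.3 to 4.7 TPM in the 6 vrs4.k libraries, against 2.8 to 7.3 in Bowman. MLOC_69611.1 ranged from 3.7 to 5.9 TPM in int-a.1 and from 3.3 to 8.9 in Bowman. MLOC_70116.1 was at 1.28 ± 0.626 TPM (SD, n = 3) in int-c.5 at W3.5, against 3.17 ± 1.42 (n = 4) in Bowman. At W5.5 it was at 3.02 ± 1.02 and 5.78 ± 1.82, and neither difference passed (adjusted p = 0.317 and 0.795).

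The HD-Zip transcript fell in other lines. In vrs4.k it was at 0.4 ± 0.608 TPM at W3.5, against 10.5 ± 7.39 in Bowman (log2 fold -2.89, SE 0.481, adjusted p = 0.000991), and at 0.767 ± 0.569 against 19.9 ± 7.79 at W5.5 (-3.54, adjusted p = 4.8e-05). In int-a.1 it was at 1.5 ± 1.06 TPM at W3.5 (-2.08, adjusted p = 0.0394) and at 5.1 ± 2.49 at W5.5 (-1.80, adjusted p = 0.0901). In int-c.5 it was at 3.73 ± 2.48 and 7.63 ± 3.43 TPM, and neither difference passed (adjusted p = 0.525 and 0.861). The int-a.1 call at W3.5 was lost without Bowman W3.5 replicate 2, 3 or 4 or int-a.1 W3.5 replicate 2 or 3 (log2 folds -1.66 to -2.24), with a pseudocount of 0.1, with only the compared groups and without the 4 libraries apart from their stage. At W5.5 it passed with library weights (-1.75), the first principal component as covariate (-1.52) or without those 4 libraries (-1.80). The vrs4.k call at W3.5 was lost with only the compared groups. The TCP transcript MLOC_70116.1 fell at W5.5 to 2.13 ± 0.252 TPM in int-a.1 (-1.08, SE 0.253, adjusted p = 0.039) and to 1.8 ± 0.1 in vrs4.k (-1.24, adjusted p = 0.0102). At W3.5 it was at 1 ± 0.436 and 1.23 ± 0.839 TPM and did not pass (adjusted p = 0.0597 and 0.146). The int-a.1 call of MLOC_70116.1 was lost without Bowman W5.5 replicate 1, 2 or 4 or any 1 int-a.1 W5.5 library (-0.91 to -1.14). It was also lost under both scalings (-0.98 and -1.01), with a pseudocount of 0.1 and with only the compared groups. The vrs4.k call was lost without Bowman W5.5 replicate 4 (-1.07) or vrs4.k W5.5 replicate 1 (-1.21) and with only the compared groups. At W3.5 MLOC_70116.1 passed in int-a.1 without Bowman replicate 1 (-1.14) or int-a.1 replicate 1 (-1.20) and with a pseudocount of 0.1. In vrs4.k it passed without its replicate 2 (-1.20). It passed in both with library weights, the first principal component as covariate or without the 4 libraries apart from their stage. Averaged over both stages, a comparison added after the data were seen, the HD-Zip transcript was lower in int-a.1 (-1.94, adjusted p = 0.00127) and vrs4.k (-3.22, adjusted p = 4.3e-07), and MLOC_70116.1 in int-a.1 (-1.05) and vrs4.k (-1.07). These 4 calls were lost in none of the alternatives run for them. The average of the HD-Zip transcript did not pass in int-c.5 (-1.26, adjusted p = 0.143), except with library weights (-1.18), or in vrs1 (-0.03). MLOC_70116.1 passed in int-c.5 (-0.80, adjusted p = 0.0467) but not in vrs1 (-0.03). That int-c.5 call was lost without Bowman W3.5 replicate 2 or 4, Bowman W5.5 replicate 1, 2 or 4, int-c.5 W3.5 replicate 2 or 3 or int-c.5 W5.5 replicate 1 or 3 (-0.69 to -0.81). It was also lost under both scalings, with a pseudocount of 0.1, a mean-variance trend, only the compared groups or the first principal component, and without the 4 libraries apart from their stage. No interaction of line and stage was called for any of these transcripts. MLOC_69611.1 and AK373051 were not called in any line at any stage.

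Of the 12 transcripts in the list of row-type factors, which holds TCP and SHI-family transcripts and the DNA-repair match AK362624, brought in by its COM1 symbol, MLOC_70116.1 was the one called in a line comparison, and the same 1 transcript passed when adjusted over the list alone. The BRANCHED1-like TCP transcript MLOC_4614.1 was at 2.37 ± 0.586 TPM in int-a.1 at W5.5 against 4.08 ± 1.32 in Bowman and did not pass (adjusted p = 0.495). The SHI-like transcript MLOC_74469.2 was at 5.5 ± 0.854 TPM in int-a.1 at W3.5 against 10.7 ± 2.84 and did not pass (adjusted p = 0.638).

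**Figure D2:**
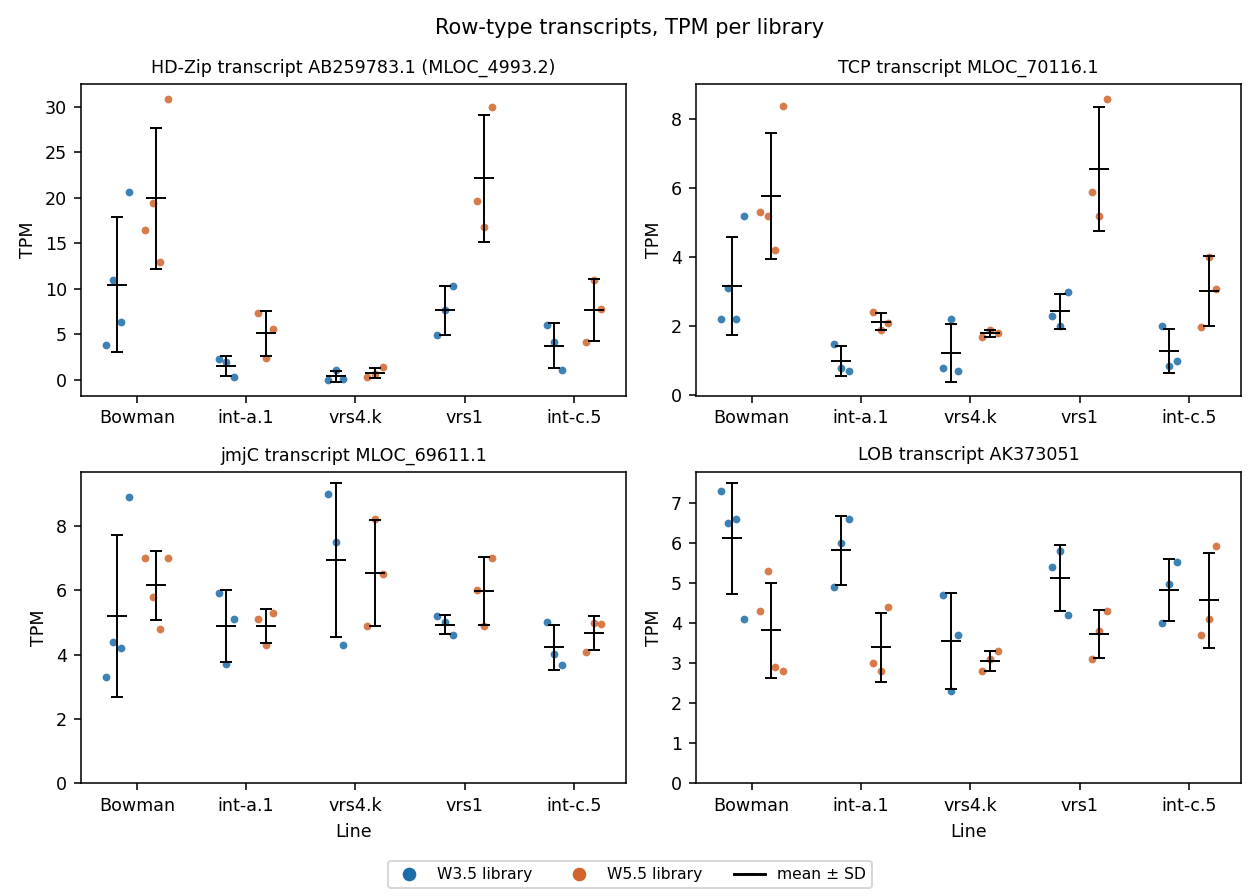
TPM (vertical axis) of 4 transcripts picked for row-type loci, by line and stage (colour); each point is 1 library and bars are the mean ± SD (n = 4 for Bowman, n = 3 for the others). The HD-Zip transcript is at 1.4 TPM or less in every vrs4.k library, and at 3.8 TPM or more in every Bowman and vrs1 library.

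In int-a.1 an endoglucanase and an AAA ATPase transcript were among the called transcripts with an informative match that fell most. The endoglucanase transcript MLOC_24935.1 (GH9B8 match, chromosome 1, 48.23), of a family that cuts cellulose chains, fell from 87.3 ± 20.2 TPM in Bowman (n = 4) to 12.6 ± 12 (n = 3) at W3.5 (log2 fold -3.03, SE 0.379, adjusted p = 2.5e-05), and from 104 ± 22.7 to 1.63 ± 1.44 at W5.5 (-5.50, adjusted p = 5.8e-10). The pentatricopeptide-repeat transcript MLOC_1344.1 (chromosome 1, 46.6) was at 5.67 ± 1.17 TPM at W5.5 against 120 ± 22.4 (-4.17, adjusted p = 4.5e-09). The AAA ATPase AK372801 (chromosome 1, 48.09) was at 0.233 ± 0.404 TPM against 31.1 ± 6.91 (-4.72), and the ankyrin-repeat transcript MLOC_31837.1 at 1.43 ± 1.44 against 48.2 ± 10.0 (-4.47). The signal peptide peptidase-like MLOC_28688.1 was listed at 0 in all 3 int-a.1 libraries at W5.5 and at 17 ± 4.86 TPM in Bowman. Among transcripts that rose were the Zim17-type zinc finger MLOC_13623.3, of a family of mitochondrial chaperone partners, at 37.7 ± 9.99 against 9.68 ± 1.19 TPM at W3.5 (1.84, SE 0.166, adjusted p = 3.8e-07), and the WD40-repeat MLOC_82101.1 at 24.8 ± 5.75 against 5.68 ± 3.12 (2.03). With only the compared groups, the W3.5 calls of MLOC_24935.1, MLOC_13623.3 and MLOC_82101.1 were lost.

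At W5.5 the H2A histone MLOC_35155.1 rose in int-a.1 to 136 ± 63.8 TPM from 43.9 ± 10.7 (1.5, adjusted p = 0.0185) as the 1 called member of 185 histone transcripts (2 when adjusted over the list alone). The histone list had a median log2 fold of 0.36 (camera adjusted p = 4.2e-18), which was lost with an estimated correlation (adjusted p = 0.998). Of 327 ribosomal protein transcripts, the cytosolic L38 transcript MLOC_8820.1 (345 ± 45.7 against 205 ± 46.5 TPM) and the L18ae-family match MLOC_55490.5 (30.9 ± 1.85 against 20.6 ± 1.98) rose at W5.5 (2 over the list alone). These 3 calls at W5.5 were lost with only the compared groups. With single libraries left out, MLOC_35155.1 was lost without Bowman replicate 2 or 3 or int-a.1 replicate 2 or 3 (1.25 to 1.46). MLOC_55490.5 was lost without Bowman replicate 2 or 3 or int-a.1 replicate 1 or 2 (0.515 to 0.564). MLOC_8820.1 was lost without Bowman replicate 2 (0.59) or int-a.1 replicate 1 (0.80) or 2 (0.67). MLOC_75443.1, named after its values were seen, fell at W3.5 to 6.63 ± 1.15 TPM from 11.6 ± 1.66 (1 over the list alone). The call was lost under both scalings, with only the compared groups and without Bowman replicate 1, 2 or 3 or int-a.1 replicate 1 or 3 (-0.61 to -0.72). The CACTA transposon transcripts AK354022 and AK353908 fell at W5.5 to 2.33 ± 0.208 and 0.0333 ± 0.0577 TPM from 26.4 ± 2.99 and 9.65 ± 1.90 (-3.03 and -3.35). Among 293 heat shock and chaperone transcripts, the ankyrin-repeat transcripts MLOC_35191.2 and MLOC_62634.1 fell at both stages, at W3.5 to 0.3 ± 0.265 and 0.2 ± 0.265 TPM from 2.73 ± 1.45 and 2.6 ± 0.627; they were named after their values were seen, and the W3.5 calls were lost with only the compared groups. In the cytokinin list 1 and 3 transcripts fell at W3.5 and W5.5 (8 and 11 when adjusted over the list alone).

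In all, limma called 197 transcripts in int-a.1 at W3.5 (21 higher, 176 lower) and 214 at W5.5 (34 higher, 180 lower). Quantile normalization gave 55 higher and 169 lower at W5.5. Low-confidence models made up 170 and 171 of the calls, and 52.5% of the transcripts tested. Of the calls, 110 were shared by the stages, all in the same direction, and the interaction with stage gave 0 calls in limma (1766 at an unadjusted p below 0.05; smallest adjusted p 0.314), and 2 without int-a.1 W3.5 replicate 1. With limma fitted to the compared groups alone, 3 and 100 transcripts were called; with library weights, 2738 and 670 were, and 207 for the interaction. At an adjusted p below 0.01 there were 108 and 128. Leaving out Bowman W3.5 replicate 4 gave 303 calls at W3.5, leaving out Bowman W3.5 replicate 2 gave 126 and leaving out int-a.1 W3.5 replicate 3 gave 125; without the 4 libraries apart from their stage, W5.5 had 325.

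In vrs4.k the HD-Zip transcript and auxin and histidine kinase transcripts were among the called transcripts with an informative match that fell most. AK369408, which matches the auxin response factor ARF5 (MONOPTEROS), a regulator of organ initiation, was listed at 0 in all 3 vrs4.k libraries at W3.5 and at 6.3 ± 1.17 TPM (n = 4) in Bowman. The serine carboxypeptidase-like MLOC_25487.2 (chromosome 2, 57.05) fell to 4.1 ± 1.25 TPM from 23.3 ± 1.46 at W3.5 (-2.28, SE 0.236, adjusted p = 9.0e-07) and to 2.8 ± 0.458 from 23.1 ± 2.53 at W5.5 (-2.66). The methyltransferase MLOC_80119.1 (chromosome 7, 76.49), which matches an enzyme of phosphocholine synthesis, rose to 10.5 ± 3.31 TPM from 0.125 ± 0.25 at W3.5 (3.34, SE 0.297, adjusted p = 7.2e-08), and was at 9.8 ± 0.361 TPM at W5.5, where Bowman was listed at 0. The ABC-protein transcript MLOC_29544.1 (chromosome 2, 58.78) rose to 53.6 ± 10.8 from 9.35 ± 5.54 TPM (2.51, adjusted p = 8.0e-05) and to 54.2 ± 8.45 from 10.3 ± 3.35 (2.33). The reverse transcriptase MLOC_74343.2 (chromosome 3, 46.88) and MLOC_26899.1, with a WD40-repeat protein as its Arabidopsis match, were at 9.17 ± 2.52 and 5.87 ± 2.50 TPM at W3.5, and listed at 0 in all 4 Bowman libraries.

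Among 91 cytokinin-list transcripts, 15 fell in vrs4.k at each stage (16 and 17 when adjusted over the list alone), and these 15 were the transcripts that match HISTIDINE KINASE 5. The Arabidopsis protein of that name is a cytoplasmic histidine kinase that is not among the cytokinin receptors. MLOC_46165.1 fell to 14.8 ± 3.08 TPM from 85.5 ± 15.4 at W3.5 (-2.45, SE 0.313, adjusted p = 2.5e-05) and to 13.6 ± 6.72 from 98.2 ± 7.68 at W5.5 (-2.87). The cytokinin list passed camera (adjusted p = 5.0e-05 and 2.5e-05), but not with an estimated correlation (adjusted p = 0.998 at both stages). Of 187 auxin-list transcripts, AK369408 and MLOC_24808.1, also an ARF match, fell at both stages, and the SAUR transcript MLOC_14016.1 rose at W5.5 to 6.57 ± 1.10 from 2.75 ± 0.545 TPM; the latter 2 transcripts were named after their values were seen. The 38 MADS-box transcripts included 2 that rose at W3.5 (2 also over the list alone), both named after their values were seen: MLOC_19375.1 (AGAMOUS-like 14 match) at 76.0 ± 45.7 TPM against 18.5 ± 6.90 (1.87, adjusted p = 0.000841) and MLOC_76418.1 at 17.3 ± 11.9 against 4.98 ± 2.58 (1.51). The MLOC_76418.1 call was lost without Bowman W3.5 replicate 2 (1.36) or 3 (1.43), vrs4.k W3.5 replicate 2 (1.01) or the 4 libraries apart from their stage (0.96). vrs4.k W3.5 replicate 2 also had the highest MADS-box mean of the W3.5 libraries. At W5.5 the photosystem II 5 kDa transcript AK360741 (chromosome 6, 46.25) rose to 85.4 ± 6.45 from 42.2 ± 10.5 TPM (1.03, adjusted p = 0.0162) as the 1 called of 90 photosynthesis transcripts; it was lost without Bowman replicate 2, 3 or 4 or vrs4.k replicate 1 or 2 (0.93 to 1.03). The homeobox list (178 transcripts) had a further lower call at W5.5, the HB40-like MLOC_77488.1 at 0.733 ± 0.252 against 4.8 ± 2.26 TPM (-1.68), named after its values were seen and lost without vrs4.k replicate 1 (-1.58) or with a pseudocount of 0.1. With only the compared groups, MLOC_14016.1, MLOC_19375.1, MLOC_76418.1, AK360741 and MLOC_77488.1 were not called.

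Core and linker histones had a median log2 fold of 0.41 in vrs4.k at W3.5 (camera adjusted p = 1.2e-16; adjusted p = 0.998 with an estimated correlation) with 0 of 185 called in limma (56 at an unadjusted p below 0.05), and lipid transfer transcripts a median of -0.27 (6.4e-05; 0.998 with an estimated correlation); vrs4.k W3.5 replicate 2, which lies apart from its stage, had the lowest lipid transfer mean of the W3.5 libraries, 3.06. At W5.5 the ribosomal list had a median of 0.18 (2.4e-26; adjusted p = 0.998 with an estimated correlation), and 1 of its 327 transcripts was called, the plastid L10 transcript AK353672 at 16 ± 2.02 against 10.4 ± 1.17 TPM (0.58), lost without vrs4.k replicate 1 (0.48) and with only the compared groups. In all, 197 transcripts were called at W3.5 (52 higher, 145 lower) and 210 at W5.5 (44 higher, 166 lower). The share of lower calls at W5.5, 79.0%, was 67.9% after quantile normalization (69 higher, 146 lower). Both stages shared 141 calls in the same direction, and the interaction gave 0 calls in limma (1877 at an unadjusted p below 0.05; smallest adjusted p 0.665). With the compared groups alone, 80 transcripts were called at W3.5, with library weights 1898, and without Bowman W3.5 replicate 4, 342.

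In vrs1 an apyrase-like transcript and a kinesin transcript rose, and a further kinesin transcript fell. AK374443, which matches GDA1/CD39 nucleoside phosphatases, rose to 7.53 ± 1.17 TPM (n = 3) from 0.15 ± 0.3 (n = 4) at W3.5 (log2 fold 2.91, SE 0.137, adjusted p = 7.6e-13) and to 6.73 ± 0.896 from 0.075 ± 0.15 at W5.5 (2.85). The kinesin motor transcript MLOC_77511.1 (chromosome 2, 80.03), close to the HD-Zip transcript on the map, rose to 7.77 ± 2.57 from 0.975 ± 0.206 TPM at W3.5 (2.12, SE 0.128, adjusted p = 8.4e-11) and to 8.4 ± 0.866 from 0.875 ± 0.05 at W5.5 (2.32). The kinesin transcript AK363795 fell to 0.4 ± 0.608 from 8.53 ± 1.09 TPM (-2.84, SE 0.171, adjusted p = 8.4e-11) and to 0.1 from 7.95 ± 0.705 (-3.02). MLOC_50345.1, which matches the Arabidopsis histone demethylase REF6, fell to 1.5 ± 0.436 from 17.9 ± 8.17 TPM (-2.83, adjusted p = 6.2e-06) and to 2.07 ± 0.896 from 15.8 ± 1.90 (-2.48). It was the 1 called member of 109 flowering and clock transcripts in int-a.1, vrs4.k and vrs1 at both stages (2 members in any line comparison when adjusted over the list alone), and its fall in int-a.1 and vrs4.k was noted after its values were seen. The int-a.1 call at W5.5 was lost without Bowman replicate 1, 2 or 3 or int-a.1 replicate 1 or 2 (-1.20 to -1.45) and with a pseudocount of 0.1, and the 3 calls at W3.5 with only the compared groups. The MADS-box transcript MLOC_59755.2 (chromosome 3, 118.9), with a rice MIKC*-type match, rose to 24.2 ± 5.65 from 4.6 ± 2.05 TPM (2.21, adjusted p = 0.00142) and to 25.5 ± 10.9 from 5.17 ± 1.77 (2.06). Both calls were lost with only the compared groups, and that at W5.5 without vrs1 replicate 1 (1.76).

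The histidine kinase transcripts fell in vrs1 as in vrs4.k: of the 15 transcripts, 14 were called lower at W3.5 and 15 at W5.5, which made up all called transcripts of the cytokinin list (15 and 16 when adjusted over the list alone). MLOC_42641.1 fell to 10.6 ± 3.99 from 71.6 ± 10.0 TPM at W3.5 (-2.69, SE 0.285, adjusted p = 4.1e-06). The list passed camera (adjusted p = 1.0e-11 and 4.1e-13), but not with an estimated correlation (adjusted p = 0.697 at both stages). The NB-ARC transcript MLOC_77081.1 (chromosome 6, 49.22), of a disease resistance family, rose to 13.1 ± 0.569 from 7.58 ± 0.378 TPM (0.71, adjusted p = 0.000236), and the WRKY13-like MLOC_55500.1 fell at W3.5 to 7.13 ± 0.289 from 15 ± 4.14 (-0.94, adjusted p = 0.0274). The MLOC_55500.1 call was lost without Bowman replicate 2, 3 or 4, any 1 vrs1 replicate or the 4 libraries apart from their stage (-0.78 to -0.97), and both calls with only the compared groups. In all, 103 transcripts were called at W3.5 (14 higher, 89 lower) and 98 at W5.5 (17 higher, 81 lower). Of these, 80 were called at both stages in the same direction, and the interaction gave 0 calls in limma (755 at an unadjusted p below 0.05; smallest adjusted p 0.408). Fitted to the compared groups alone, W3.5 had 25 calls.

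In int-c.5 fewer transcripts were called, and chromatin and MADS-box transcripts were among them. MLOC_42667.1 and MLOC_42597.1, which match SU(VAR)3-9 homolog 5, a histone H3 lysine methyltransferase, fell at W3.5 to 0.46 ± 0.797 and 1.62 ± 2.11 TPM (n = 3) from 17.4 ± 2.26 and 19.2 ± 9.01 (n = 4; log2 folds -3.78 and -3.15, adjusted p = 1.5e-09 and 1.4e-05). At W5.5 both were listed at 0 in all 3 int-c.5 libraries and at 22.7 ± 3.86 and 25.1 ± 5.29 TPM in Bowman. They were the 2 called of 89 histone demethylase and methyltransferase transcripts at each stage (2 in any line comparison when adjusted over the list alone); the key words of that list do not take in the REF6 match MLOC_50345.1. The MADS-box transcripts MLOC_19375.1 (chromosome 7, 70.54) and MLOC_76418.1, both AGAMOUS-like 14 matches, rose at W3.5 to 80.1 ± 6.74 and 17 ± 1.20 TPM from 18.5 ± 6.90 and 4.98 ± 2.58 (2.11 and 1.68, adjusted p = 0.000547 and 0.0245), and at W5.5 to 182 ± 51.1 and 35.4 ± 6.90 from 50 ± 13.2 and 11.3 ± 3.77 (1.85 and 1.60). MLOC_76418.1 was lost at W3.5 without Bowman replicate 2, 3 or 4 or any 1 int-c.5 replicate (1.535 to 1.724). It was lost at W5.5 without Bowman replicate 1, 2 or 3 or any 1 int-c.5 replicate (1.44 to 1.70) and with a pseudocount of 0.1. MLOC_19375.1 was lost at W5.5 without int-c.5 replicate 2 (1.64). The ankyrin-repeat transcript AK248975.1, which matches a co-chaperone of the tetratricopeptide-repeat class, rose to 19.1 ± 1.65 from 0.675 ± 0.386 TPM at W3.5 (SE 0.167, adjusted p = 2.6e-13) and to 24.7 ± 3.11 from 0.65 ± 0.1 at W5.5 (3.96). The dynamin-related AK355857 rose to 17.5 ± 1.44 from 3.93 ± 1.49 TPM (1.96, adjusted p = 5.6e-06). With only the compared groups, both MADS-box transcripts were lost at both stages, and MLOC_42597.1 and AK355857 at W3.5. The int-c.5 columns differ from the others in the table by their decimals, and whether they were processed separately is not given in the sources used here.

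The 90 photosynthesis transcripts had a median log2 fold of 0.25 in int-c.5 at both stages (camera adjusted p = 1.1e-12 and 6.2e-12), lost with an estimated correlation (adjusted p = 0.998 at both stages), with 0 called in limma at either stage (17 and 15 at an unadjusted p below 0.05; 0 and 1 over the list alone). int-c.5 W5.5 replicate 1 had the highest photosynthesis mean of all libraries, 4.44. Lipid transfer transcripts had a median of 0.36 at W5.5 (3.7e-07; adjusted p = 0.998 with an estimated correlation). Their mean was also highest among the W5.5 libraries in int-c.5 W5.5 replicate 1, at 4.24, against 3.10 to 3.98 in Bowman. Histones had a median of 0.25 at W3.5 and -0.13 at W5.5 (1.5e-09 and 0.00694; adjusted p = 0.9996 with an estimated correlation at both stages). limma called 30 transcripts at W3.5 (13 higher, 17 lower) and 32 at W5.5 (16 higher, 16 lower); 23 were called at both stages in the same direction. The interaction gave 0 calls in limma (878 at an unadjusted p below 0.05; smallest adjusted p 1). With the compared groups alone, 4 and 19 were called, and with library weights 62 and 177. At an adjusted p below 0.01, W5.5 had 20. Without Bowman W3.5 replicate 1, W3.5 had 50 calls, and without int-c.5 W5.5 replicate 1 or 3, W5.5 had 18 or 20.

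The next question was which transcripts the lines had in common. A pair of MuDR-type transposase transcripts, MLOC_43354.2 and MLOC_37037.1, rose in all 4 lines at both stages: at W3.5 MLOC_43354.2 was at 29.6 to 43.1 TPM in the lines and 5.13 ± 5.41 in Bowman, and MLOC_37037.1 at 19 to 31.5 and 3.08 ± 2.41. The low-confidence transcripts MLOC_26336.1 (higher) and MLOC_22369.3 and MLOC_22368.1 (lower; chromosome 6, 1.841) were also called in all 4 lines at both stages, and MLOC_37036.1 (higher) at W3.5; these 4 have no match and were named after their values were seen. That makes 6 transcripts at W3.5 and 5 at W5.5. Of the 4 without a match, MLOC_22369.3 kept its calls whichever single library was left out, and the other 3 did not. At W3.5 MLOC_22368.1 was lost in int-a.1 without Bowman replicate 1 or 3 or int-a.1 replicate 2 or 3 (-0.72 to -0.83), in vrs4.k without its replicate 3 (-0.91) and in vrs1 without its replicate 3 (-0.99). MLOC_26336.1 was lost in vrs1 without Bowman replicate 2 or any 1 vrs1 replicate (2.06 to 2.61). MLOC_37036.1 was lost in vrs4.k without Bowman replicate 2 or vrs4.k replicate 1 or 2 (1.27 to 1.55) and in int-c.5 without Bowman replicate 2 or 4 or any 1 int-c.5 replicate (1.51 to 1.76). At W5.5 MLOC_22368.1 was lost in int-c.5 without Bowman replicate 2, 3 or 4 or any 1 int-c.5 replicate (-0.91 to -1.09). MLOC_26336.1 was lost there in vrs1 without its replicate 2 (2.49) and in int-c.5 without its replicate 3 (2.86). With a pseudocount of 0.1, calls were lost at W3.5 for MLOC_43354.2 in vrs1 and int-c.5, MLOC_26336.1 in int-a.1, vrs1 and int-c.5, MLOC_22368.1 in int-a.1 and MLOC_37036.1 in all 4 lines. At W5.5 that setting ended the calls of MLOC_26336.1 in int-a.1, vrs1 and int-c.5 and of MLOC_22368.1 in int-c.5. With only the compared groups, each of these transcripts lost calls. At W3.5 these were MLOC_43354.2, MLOC_26336.1, MLOC_22368.1 and MLOC_37036.1 in all 4 lines, MLOC_37037.1 in int-a.1, vrs1 and int-c.5, and MLOC_22369.3 in int-a.1 and int-c.5. At W5.5 they were MLOC_43354.2 in all 4 lines, MLOC_26336.1 in int-a.1, vrs1 and int-c.5, and MLOC_22368.1 in int-c.5. Without the 4 libraries apart from their stage, calls were lost at W3.5 for MLOC_26336.1 in int-a.1 and vrs1 and MLOC_37036.1 in vrs4.k and int-c.5, and at W5.5 for MLOC_26336.1 and MLOC_22368.1 in int-c.5. With the first principal component as covariate, MLOC_22368.1 was lost in int-c.5 at W5.5. The columns of int-c.5 differ from the others in their decimals, as given with the int-c.5 comparison. vrs4.k and vrs1 shared 70 calls at W3.5 (5 higher, 65 lower) and 80 at W5.5 (7 higher, 73 lower), with 0 in opposite directions. Unchanged lines simulated against the same Bowman libraries shared 0.03 calls on average at W3.5 and 0 at W5.5, and independent lists would share 0.0241 higher and 0.428 lower at W3.5, and 0.0248 and 0.446 at W5.5. With each line compared with a separate pair of Bowman libraries, the 2 lines shared 47.5 and 56.8 calls on average.

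int-a.1 shared 30 and 37 calls with vrs4.k, 27 and 33 with vrs1, and 7 and 8 with int-c.5 (W3.5 and W5.5); int-c.5 shared 8 and 7 with vrs4.k and 7 and 6 with vrs1. With the Bowman libraries split, these counts averaged 11.5 and 14.5, 9.5 and 13, 2.83 and 3.33, 4.33 and 3.33, and 2.83 and 2.83. Without Bowman W3.5 replicate 4, int-a.1 shared 67 calls with vrs4.k and 45 with vrs1 at W3.5, and without int-a.1 W5.5 replicate 1 it shared 15 and 12 at W5.5. int-a.1 and vrs4.k shared 18, 19 and 17 at W3.5 without Bowman replicate 3, int-a.1 replicate 2 or int-a.1 replicate 3, and 24 at W5.5 without Bowman replicate 3. int-a.1 and vrs1 shared 17 at W3.5 without Bowman replicate 3. With int-c.5 at W5.5, int-a.1 shared 4 without Bowman replicate 4 or any 1 int-c.5 replicate and 5 without Bowman replicate 3 or int-a.1 replicate 2 or 3. vrs4.k then shared 3 without int-c.5 replicate 3 and 4 without int-c.5 replicate 1 or Bowman replicate 4, and vrs1 shared 3 without vrs1 replicate 2 or int-c.5 replicate 3. At W3.5 vrs1 and int-c.5 shared 4 without Bowman replicate 2 or vrs1 replicate 3. Library weights gave 12 to 612 shared calls over the pairs at W3.5, with 612 for int-a.1 and vrs4.k and 110 for vrs4.k and vrs1. A fit of only the compared groups gave 17 for vrs4.k and vrs1 at W3.5 and 0 for each other pair. At W5.5 that fit gave 8 for int-a.1 with vrs4.k and with vrs1, and 2 for each pair with int-c.5. A pseudocount of 0.1 gave 19 and 20 for int-a.1 and vrs4.k (W3.5 and W5.5), 17 and 19 for int-a.1 and vrs1 and 3 and 4 for int-a.1 and int-c.5. Across transcripts, which are not independent replicates, the log2 folds of the 12 pairs of lines and stages correlated at r = 0.240 to 0.578. The lowest was vrs4.k and int-c.5 at W3.5, below its simulated 0.288, with a covariance difference of 0.00992 and r = -0.0720 with the Bowman libraries split. At W5.5 int-a.1 and int-c.5 had 0.340 against 0.287 simulated, and vrs1 and int-c.5 0.337 against 0.290. The folds of vrs4.k and vrs1 correlated at r = 0.513 and 0.578, against 0.260 and 0.275 for simulated unchanged lines. Their covariance was 0.05 and 0.0521, against 0.0149 and 0.0154 simulated, a difference of 0.0351 and 0.0367. With the Bowman libraries split, r was 0.0698 and 0.221 and the covariance 0.00743 and 0.0252. Most of the excess at W3.5 and part of it at W5.5 thus goes with the shared controls.

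The summed level of the 15 histidine kinase transcripts was lower in vrs4.k and vrs1 than in Bowman and int-a.1, with no overlap of libraries (53 to 112 TPM in the 12 vrs1 and vrs4.k libraries, 124.5 or more in int-a.1). int-c.5 (384.1 to 542.7) overlapped Bowman (407.4 to 550.1), and vrs1 overlapped vrs4.k. It was 445 ± 33.4 TPM in Bowman at W3.5 and 511 ± 35.9 at W5.5 (n = 4), 94.6 ± 6.53 and 79.6 ± 28.8 in vrs4.k, 79.5 ± 22.7 and 68.3 ± 14.4 in vrs1, 232 ± 56.6 and 259 ± 116 in int-a.1, and 420 ± 35 and 483 ± 54.8 in int-c.5 (n = 3). In int-a.1 1 library per stage (166.7 and 124.5 TPM) lay below the others (264.3 or more), so these means do not stand for uniform libraries. Whether plants of this stock were genetically uniform is not given in the sources used here. The median log2 fold over the 15 transcripts was -2.01 and -2.42 in vrs4.k, -2.13 and -2.59 in vrs1, -0.87 and -0.98 in int-a.1 and -0.08 and -0.03 in int-c.5. In int-a.1 all 15 values were negative at each stage, and 1 and 2 passed. In int-c.5 0 passed in limma. These transcripts were put together after their values were seen; 4 have a map position, on 2 chromosomes, and 5 are low-confidence models.

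**Figure D3:**
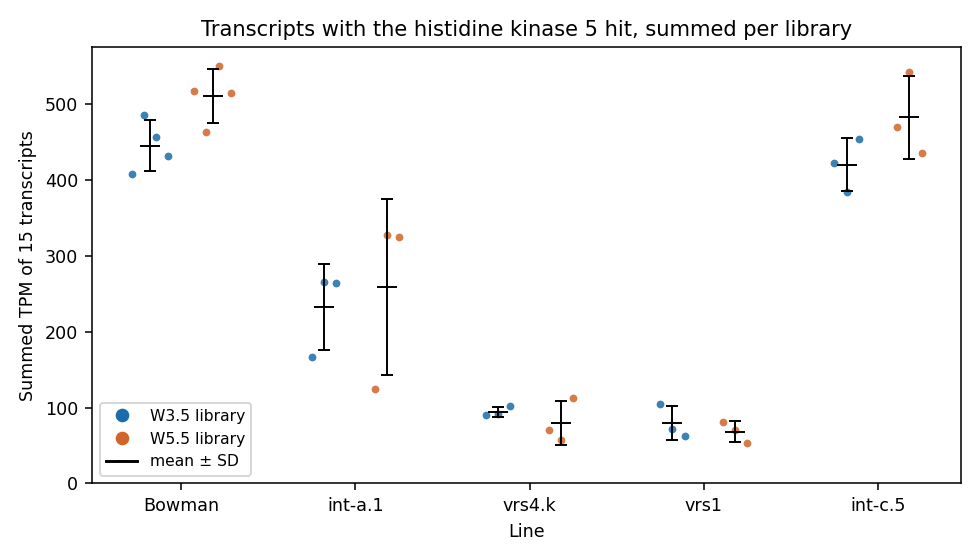
Summed TPM (vertical axis) of the 15 transcripts that match HISTIDINE KINASE 5, by line and stage (colour); each point is 1 library and bars are the mean ± SD (n = 4 for Bowman, n = 3 for the others). Every vrs4.k and vrs1 library lies below every Bowman library, with means of 68.3 to 94.6 TPM against 445 and 511.

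A further question was whether calls lay on the locus chromosome. In int-a.1, 29 of 96 called transcripts with a map position lay on chromosome 1 at W3.5 (30.2%) and 28 of 85 at W5.5 (32.9%), against 11.9% of all placed transcripts (Fisher's exact test, adjusted p = 5.2e-06 and 2.2e-06). In vrs4.k, 25 of 83 (30.1%) and 23 of 75 (30.7%) lay on chromosome 3, against 14.2% (adjusted p = 0.000505 and 0.000663, Fisher's exact test). In vrs1, 11 of 39 (28.2%) and 12 of 33 (36.4%) lay on chromosome 2, against 17.8% (adjusted p = 0.125 and 0.0162, Fisher's exact test). At an unadjusted p below 0.05, the vrs1 share at W3.5 passed without Bowman replicate 1 (32.4%), vrs1 replicate 1 (32.4%) or vrs1 replicate 3 (33.3%). It passed with only the compared groups (46.2%), at an adjusted p of 0.01 (33.3%) or with the first principal component (29.6%). With library weights the int-a.1 share at W3.5 was 12.8% and no longer passed. In int-c.5, 0 of 7 and 2 of 8 (25%) lay on chromosome 4, against 9.95% (adjusted p = 1 and 0.212, Fisher's exact test). These shares rest on few calls. At W3.5 the share was 7.14% without Bowman replicate 1. At W5.5 it was 0% without Bowman replicate 2 or 4 or int-c.5 replicate 1 or 3 and 40% without Bowman replicate 3. The W5.5 share passed at an unadjusted p below 0.05 with quantile normalization (36.4%), a mean-variance trend (40%) or library weights (20.5%). In int-a.1 the densest window of 50 transcripts spanned 28.12 to 38.03 of chromosome 1. This window had 6 calls at W3.5 and 7 at W5.5, all low-confidence models (permutation p = 0.001 at both stages, the smallest possible). Neighbouring models can be fragments of 1 gene, counted apart by both tests. In the other lines the densest windows had permutation p = 0.0669 or more.

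**Figure D4:**
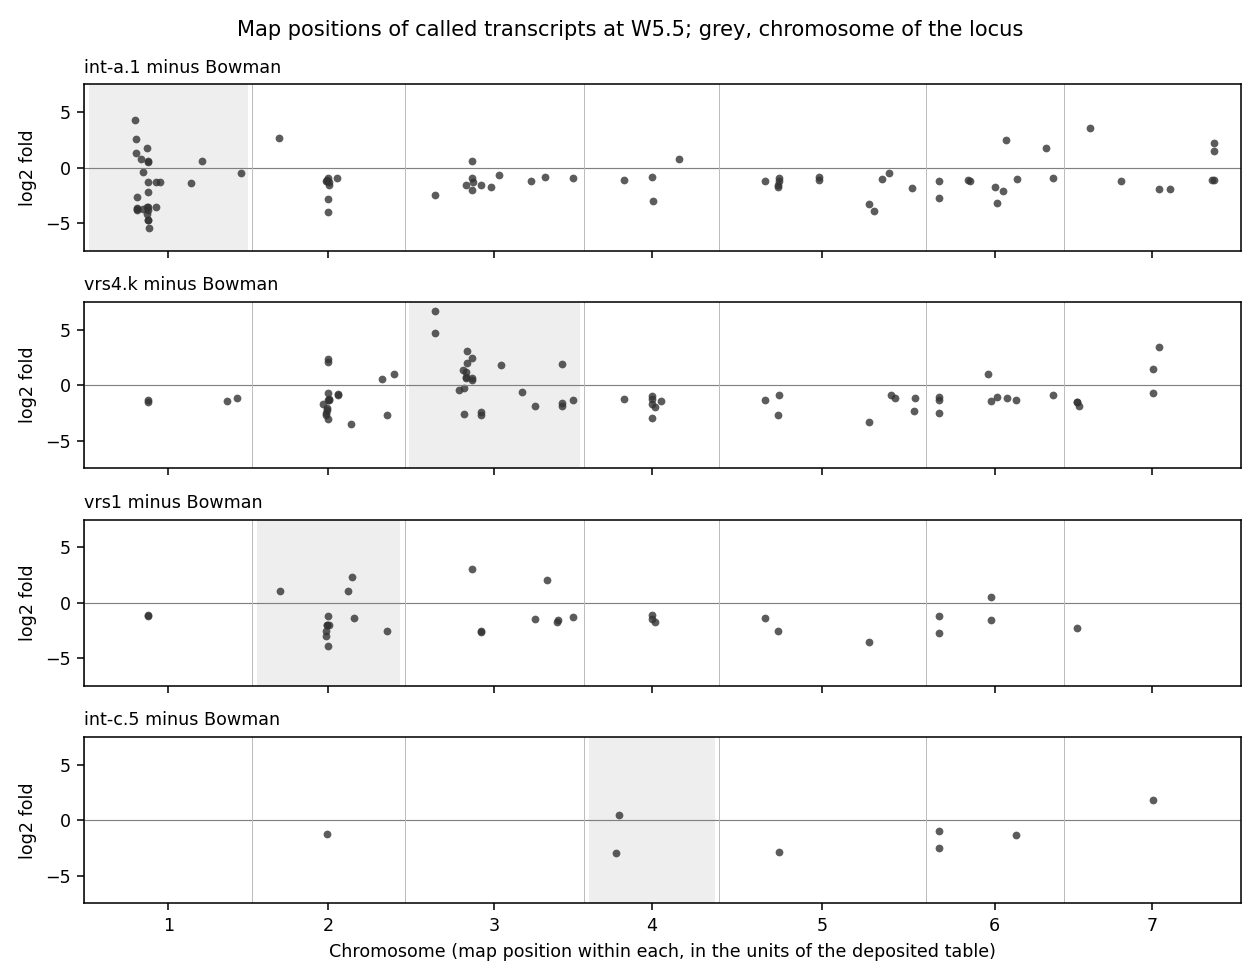
Log2 fold of called transcripts with a map position at W5.5 (vertical axes) against their place on chromosomes 1 to 7 (horizontal axis, PopSeq positions of the deposited table), 1 panel per line; each point is 1 transcript, and the chromosome of the locus is shaded. In int-a.1, 28 of 85 points lie on chromosome 1, and in vrs4.k, 23 of 75 on chromosome 3.

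Between stages, more MADS-box transcripts rose than fell and more ribosomal protein transcripts fell than rose when the 5 lines were averaged, a comparison added after the data were seen. The APETALA3-like transcript AK373398, which matches a B-class regulator of petal and stamen identity, rose to 23.9 ± 8.50 TPM at W5.5 from 7.86 ± 11 at W3.5 (n = 16 each; log2 fold 1.88, SE 0.298, adjusted p = 0.00084). MLOC_19375.1 rose to 87 ± 59.4 from 44.2 ± 33.1 TPM (0.99), the SHI-like MLOC_74469.2 to 19.8 ± 7.09 from 9.43 ± 5.80 (1.11) and the TCP transcript MLOC_70116.1 to 3.98 ± 2.29 from 1.91 ± 1.19 (0.74, adjusted p = 0.000847). The TCP5-like MLOC_14785.1 fell to 7.31 ± 3.27 from 16.1 ± 5.91 TPM (-1.03, adjusted p = 0.00691). The jasmonate-induced MLOC_56924.1 fell to 45.4 ± 27.5 from 136 ± 108 TPM (-1.54), and MLOC_59389.2, which matches a JAZ repressor of jasmonate signalling, to 2.76 ± 1.03 from 5.78 ± 2.33 (-0.80). Of 38 MADS-box transcripts, 19 rose and 2 fell (26 in all when adjusted over the list alone). Of 185 histone transcripts, 44 rose and 1 fell (59 over the list alone), and of 178 homeobox transcripts, 42 rose and 8 fell (56 over the list alone). Of 327 ribosomal protein transcripts, 5 rose and 134 fell (181 over the list alone), and all 10 called jasmonate transcripts fell (11 over the list alone). With quantile normalization and median centring, 27 and 25 homeobox transcripts rose and 14 and 13 fell, and with centring 18 histone transcripts rose. In each of these 5 lists the direction of most calls was the same under both scalings.

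In all, 5011 transcripts were called in this average (3543 higher, 1468 lower), 155 of them with a change of at least 2-fold. The split turned with the scaling: quantile normalization gave 1964 higher and 2731 lower, and median centring 1614 higher and 3006 lower. At an adjusted p below 0.01 there were 1036, and with library weights 15088. The count was 7744 without vrs4.k W3.5 replicate 2, 2731 without its replicate 3, 3094 without vrs4.k W5.5 replicate 2, 2982 without int-a.1 W3.5 replicate 2, 2930 without vrs1 W5.5 replicate 3 and 3021 without int-c.5 W5.5 replicate 2. Within single lines limma without weights called 0 in Bowman (6705 at an unadjusted p below 0.05; smallest adjusted p 0.0667), 0 in vrs4.k (635), 0 in vrs1 (2159) and 0 in int-c.5 (4774). In int-a.1, 3 transcripts rose, named after their values were seen: the BTB and ankyrin transcript MLOC_61451.6 to 18.6 ± 3.90 from 8.53 ± 0.808 TPM (1.02, adjusted p = 0.0124), MLOC_29391.1, with a SERPIN protease inhibitor as its Arabidopsis match, to 10.6 ± 1.54 from 1.87 ± 1.85 (2.27) and MLOC_29890.1, without a match, at 3.57 ± 0.643 TPM where W3.5 was listed at 0. MLOC_61451.6 was lost without W3.5 replicate 2 (0.97) or W5.5 replicate 1 (0.87) and with only the compared groups. MLOC_29391.1 was lost without W3.5 replicate 2 or 3 or any 1 W5.5 replicate (1.64 to 2.41) and with a pseudocount of 0.1 or only the compared groups. MLOC_29890.1 was lost without W3.5 replicate 2 (2.18) or 3 (2.18) or W5.5 replicate 1 (2.07). With library weights the calls were 1654 in Bowman, 7697 in int-a.1, 1138 in vrs4.k, 40 in vrs1 and 7937 in int-c.5. Adjusted over the list alone, Bowman had 16 MADS-box calls (14 higher, 2 lower) and 73 ribosomal calls (1 higher, 72 lower). The ribosomal list had a median log2 fold of -0.20 in Bowman (camera adjusted p = 2.7e-29; adjusted p = 0.998 with an estimated correlation). Quantile normalization gave 13 calls in Bowman (76.9% lower) and 7 in int-a.1 (57.1% lower), and median centring 14 (64.3% lower) and 5 (40% lower). A pseudocount of 0.1 gave 3 in Bowman, and only the compared groups gave 1 in Bowman, 2 in vrs1 and 1 in int-c.5. At an adjusted p below 0.01, int-a.1 had 0. Leaving out Bowman W3.5 replicate 3, Bowman W3.5 replicate 4 or Bowman W5.5 replicate 1 gave 43, 415 or 177. In int-a.1 14 were called without W3.5 replicate 1, 6 without W5.5 replicate 3 and 0 without W3.5 replicate 2 or W5.5 replicate 1, and in int-c.5 5 were called without W5.5 replicate 1 and 1 without W3.5 replicate 1.

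Over the 8 line comparisons, 13 of the 29 lists had 0 called members in limma, and 11 of these had none over the list alone either. The latter were SPL (6 of 18 transcripts at an unadjusted p below 0.05 in at least 1 comparison), YABBY (2 of 6), cell cycle (74 of 214), jasmonate (15 of 48), ethylene (41 of 116), brassinosteroid (22 of 75), trehalose and sucrose (24 of 76), dehydrin and LEA (9 of 33), cell wall (45 of 161; the key words do not take in the endoglucanase MLOC_24935.1), vascular and lignin (29 of 83) and lipid transfer (16 of 58). The LOB-domain (4 of 8) and gibberellin (18 of 52) lists had 1 each when adjusted over the list alone. The abscisic acid list (131) had 1 call, the HVA22-like MLOC_73911.1, lower in vrs4.k at W3.5 at 1.27 ± 0.907 against 7.4 ± 6.00 TPM. The anther and pollen list (174) had 2, AK374443 and the potassium-channel match MLOC_58693.2, lower in vrs4.k at W3.5 (2.13 ± 0.666 against 5.08 ± 1.18 TPM). These counts were 1 and 2 over the list alone. The heat shock list had 4 (4 over the list alone), AK248975.1, the ankyrin-repeat MLOC_35191.2 and MLOC_62634.1 and the DNAJ transcript AK362332 (3.5 ± 0.5 against 4.95 ± 0.444 TPM in vrs4.k at W3.5). MLOC_73911.1, MLOC_58693.2 and AK362332 were named after their values were seen and were lost with only the compared groups. MLOC_73911.1 was also lost without Bowman replicate 1 or 3, vrs4.k replicate 1 or 2 (-1.31 to -1.73), the 4 libraries apart from their stage or with the first principal component. MLOC_58693.2 was lost without Bowman replicate 1 or 3 or vrs4.k replicate 1 or 2 (-0.78 to -1.01) and under both scalings. AK362332 was lost without Bowman replicate 4 or vrs4.k replicate 1 or 2 (-0.32 to -0.41), without the 4 libraries, with a mean-variance trend and under both scalings. The defence list (454) had 9 (10 over the list alone) and the transposon list (1386) had 34, of which 27 were lower (41 over the list alone). The TCP list (43) had 1, MLOC_70116.1, and passed camera upward in 6 comparisons, none with an estimated correlation (smallest adjusted p 0.998). Of all 261 list tests, 71 passed with the preset correlation and 0 with an estimated correlation (smallest adjusted p 0.697); median, mean and test differed in sign in 78, of which 0 had passed.

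The authors' deposited table lists 118 and 160 transcripts below a false discovery rate of 0.05 for int-a.1 at W3.5 and W5.5, of which 108 and 139 were also called here. For vrs4.k the authors' deposited table has 150 and 153 (138 and 141 called here), for vrs1 78 and 83 (75 and 77) and for int-c.5 23 and 28 (18 and 23). The log2 folds of the authors' deposited table and those computed here correlated at r = 0.977 or more across transcripts in every line comparison.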

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

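The test of Bowman against the ranges of the line libraries and the tests of directions on the locus chromosome were chosen only after their results were seen; averages over stages or lines and their splits were added after the data were seen, and the other tests were planned before their results. In the Bowman groups of 4 libraries, 215 sets of values were searched for a library far from the other 3, by its gap to the nearest one divided by the range. The limit was passed by 21 sets (9.77%), where chance gives about 1 in 20, and in 10 of them the other 3 libraries had identical values.

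At W3.5 the summed TPM of Bowman replicate 3 lay apart (981300 against 985700 to 986400, ratio 0.8627), as did its photosynthesis mean (3.83 against 3.56 to 3.60, ratio 0.8783) and its level of the TCP transcript MLOC_72581.1 (ratio 0.8894). The ratio was 0.9175 for the ribosomal L38 transcript MLOC_8820.1, 0.8639 for the ribosomal MLOC_68534.1 and 0.8769 for the CACTA transcript AK353908, all in replicate 1. Replicate 2 stood apart in the WD40-repeat MLOC_50765.1 (0.8699). Replicate 4 stood apart in the SHI-like MLOC_79356.1 (0.8646), in MLOC_51948.1 (0.9461) and in MLOC_55351.1 (0.8572). At W5.5 MLOC_8820.1 was low in Bowman replicate 2 (0.8386). The ratio was 1 where the other 3 libraries were identical: MLOC_69072.2, MLOC_80119.1, AK374443 and MLOC_33805.1 at W3.5, and MLOC_4488.1, AK374443, MLOC_77511.1, MLOC_33805.1, AK248975.1 and MLOC_35680.1 at W5.5, all below 1.1 on the log2(TPM + 1) scale.

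A pattern of interest is the pair of MuDR-type transposase transcripts, MLOC_43354.2 and MLOC_37037.1, and the other transcripts called the same way in all 4 lines at W3.5. Chance from the shared Bowman libraries stays open. Of 100 simulated sets of unchanged lines 0 reached the 6 observed (at most 3), but they shared less covariance than splitting Bowman libraries removed. One deviating Bowman library is argued against, since at least 4 were called whichever Bowman W3.5 library was left out. A Bowman stock or batch difference cannot be told apart from genotype, because all lines share the Bowman groups. In 0 of the 6 transcripts did a Bowman W5.5 library lie within the range of the 24 line libraries, and in 5 every Bowman library of both stages lay outside it; the exception was MLOC_26336.1, at 11.2 TPM in Bowman W3.5 replicate 1 against 11.1 to 28.2 TPM in the lines.

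In int-a.1 and vrs4.k called transcripts were in excess on the chromosome of the locus, among them the endoglucanase MLOC_24935.1 on chromosome 1 in int-a.1 and the reverse transcriptase MLOC_74343.2 on chromosome 3 in vrs4.k. Donor alleles that match the reference poorly would lower transcripts, and poorly matching Bowman alleles would raise them. Directions therefore cannot decide on matching. In vrs4.k, 52% of these calls at W3.5 were higher than in Bowman (13 of 25, exact 95% interval 31.3 to 72.2). On other chromosomes 17.2% were (10 of 58, Fisher's exact p = 0.00259). In int-a.1, 20.69% were higher (6 of 29, exact interval 7.99 to 39.7). On other chromosomes 1.49% were (1 of 67, Fisher's exact p = 0.0028). Poor matching stays open in both lines, as do cis-acting donor alleles and effects of the locus, which were not tested.

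The 15 histidine kinase transcripts lower in vrs4.k and vrs1 may rest on few independent measurements. Their deviations from the group means correlated at 0.4513 on average, against a mean of 0.0485, a 95th percentile of 0.152 and a highest value of 0.281 in 1000 random sets matched on level, which is consistent with reads shared among near-identical copies. Copies that are regulated together would give the same correlation, and this was not tested. One deviating Bowman library is argued against, because 15 copies were called in vrs1 at W5.5 whichever Bowman W5.5 library was left out. Different numbers of copies in the lines and an effect of the loci stay open.

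Other splits of the same libraries were refitted to gauge chance. At W5.5 the real split ranked 1 of 35 in each line: 214 in int-a.1 (highest other 104), 210 in vrs4.k (85), 98 in vrs1 (13) and 32 in int-c.5 (10). These ranks share Bowman libraries and cannot exclude chance. At W3.5 chance is not excluded: 3 of 35 splits gave at least the 197 calls of int-a.1 (highest other 624), 3 of 35 the 197 of vrs4.k (1438), 2 of 35 the 103 of vrs1 (228) and 2 of 35 the 30 of int-c.5 (34). The splits with 624 and 1438 calls, several times the real count, point to a structure of the samples: both put Bowman W3.5 replicate 4, which scored with the W5.5 libraries on the first principal component, with line libraries. For int-a.1, vrs4.k and int-c.5 the other split as large, with 205, 672 and 34 calls, was the real contrast with 1 Bowman library moved across (replicates 4, 4 and 1).

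Where the real count is 0, every split reaches it, so these splits say nothing of chance. Between stages in Bowman all 35 splits reached 0, and the highest other, with 693 calls, is the real contrast with Bowman W3.5 replicate 3 and W5.5 replicate 1 exchanged, which points to a structure of the samples. In the other lines the 10 splits are too few for a share under 0.05: the real count and the highest other were 3 and 41 in int-a.1 (3 splits as large), 0 and 4 in vrs4.k, 0 and 1 in vrs1, and 0 and 1 in int-c.5 (10 splits as large in each). For the interactions all 100 splits drawn reached the real count of 0, with highest others of 16 in int-a.1, 5 in vrs4.k, 1262 in vrs1 and 480 in int-c.5. For the averages over both stages, 3 of 100 splits reached the 643 of int-a.1 (highest other 2047) and 2 of 100 the 466 of vrs4.k (1624). In vrs1 2 of 100 reached 150 (579), and in int-c.5 3 of 100 reached 104 (115). These shares are under 0.05. In every line, though, another split gave more calls than the real one, so chance is not excluded. The splits with several times the real count again point to a structure of the samples. For the average over 5 lines between stages, 1 of 100 splits, the real one, reached 5011 (highest other 6).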

How the results depend on the processing

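The averages over stages or lines and their alternatives, the fit with the first principal component and the fit without 4 libraries were chosen after seeing the data. No paired analysis was possible because the labels give no replicate numbers, and the numbers in the table's headers are not tied to samples or to a shared batch. The 321 named results include some never called, which cannot be lost, and some named outside the rule after their values were seen. Of 5816 refitted values, 360 lost a call, 20 gained one and 0 reversed one. Of the 360, 198 left out 1 library and 91 used only the groups compared. An adjusted p of 0.01 and the 2-fold limit use the same fit and cost 39 and 35 calls. In the 17 planned comparisons the stricter filter and the 2-fold limit moved no count of calls by over 1.5 times. In the added averages over both stages the 2-fold limit left 209 of 643 calls in int-a.1, 196 of 466 in vrs4.k, 109 of 150 in vrs1 and 41 of 104 in int-c.5, and in the average over 5 lines 155 of 5011. In the alternatives fitted to W5.5 that left out no single library, vrs4.k had 149 to 314 calls, vrs1 76 to 140, and both shared 56.8 to 91. The list medians given in the report kept their sign under both scalings. Depth is unknown, so weakly expressed transcripts carry an error that cannot be stated. The filter of 0 TPM was void, the sums over genes were not run, the average over 5 lines uses all groups, and int-c.5 at W3.5 had no placed call with only the groups compared. For each change below the cause was not tested.

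Quantile normalization gave 13 calls between stages in Bowman (76.9% lower) and 7 in int-a.1 (57.1% lower), and 36.4% of int-c.5 W5.5 calls on the locus chromosome. Shares on the locus chromosome are compared at an unadjusted Fisher's exact p of 0.05. Median centring gave 14 calls in Bowman (64.3% lower) and 5 in int-a.1 (40% lower). In the average over 5 lines 29.3% of calls were lower, 58.2% after quantile normalization and 65.1% after centring. In the averages over both stages these shares were 77.9%, 64.4% and 64.1% in vrs4.k, and 63.5% and 53.2% (centring) in int-c.5. At W5.5 quantile normalization gave 55 higher calls in int-a.1 against 34, and 69 in vrs4.k against 44. Scaling moved the median of all log2 folds by over 0.1 in vrs4.k at W5.5 (by 0.1001, centring) and in int-c.5 between stages (by -0.118, quantile, and -0.138, centring). A pseudocount of 0.1 gave 3 calls between stages in Bowman, and shared calls at W3.5 of 19 (int-a.1 and vrs4.k), 17 (int-a.1 and vrs1), 3 (int-a.1 and int-c.5), 5 (vrs4.k and int-c.5) and 4 (vrs1 and int-c.5), and at W5.5 of 20, 19 and 4 for the 3 pairs with int-a.1 in the same order.

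Library weights gave 2738 and 670 calls in int-a.1 at W3.5 and W5.5, 1898 in vrs4.k at W3.5, and 62 and 177 in int-c.5, with 12.8% on the locus chromosome in int-a.1 at W3.5 and 20.5% in int-c.5 at W5.5. Between stages they gave 1654 in Bowman, 7697 in int-a.1, 1138 in vrs4.k, 40 in vrs1 and 7937 in int-c.5, and 207 for the interaction of int-a.1. In the averages they gave 3120 in int-a.1, 1969 in vrs4.k, 285 in vrs1, 438 in int-c.5 and 15088 over 5 lines. Shared calls were then 612 (int-a.1 and vrs4.k), 89 (int-a.1 and vrs1), 33 (int-a.1 and int-c.5), 110 (vrs4.k and vrs1), 21 (vrs4.k and int-c.5) and 12 (vrs1 and int-c.5) at W3.5, and 56 (int-a.1 and vrs4.k), 27 (int-a.1 and int-c.5), 23 (vrs4.k and int-c.5) and 15 (vrs1 and int-c.5) at W5.5. With only the groups compared, calls were 3 and 100 in int-a.1, 80 in vrs4.k and 25 in vrs1 at W3.5, and 4 and 19 in int-c.5, with 46.2% on the locus chromosome in vrs1 at W3.5. Between stages they were 1 in Bowman, 2 in vrs1 and 1 in int-c.5, and in the averages over both stages 289 in int-a.1, 297 in vrs4.k and 65 in int-c.5. At W3.5 the shared calls were then 17 for vrs4.k and vrs1 and 0 for the other pairs, and at W5.5 they were 8 and 8 for int-a.1 with vrs4.k and vrs1 and 2 for each pair with int-c.5.

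At an adjusted p of 0.01, calls were 108 and 128 in int-a.1, 20 in int-c.5 at W5.5 and 0 between stages in int-a.1, with 33.3% on the locus chromosome in vrs1 at W3.5; shared calls were 13 (int-a.1 and vrs4.k), 12 (int-a.1 and vrs1), 4 (int-a.1 and int-c.5) and 4 (vrs1 and int-c.5) at W3.5, and 18, 18, 4 and 4 (vrs4.k and int-c.5) at W5.5. The averages then had 316 in int-a.1, 237 in vrs4.k, 56 in int-c.5 and 1036 over 5 lines. With the Bowman libraries split 2 and 2, shared calls averaged 11.5, 9.5 and 2.83 (int-a.1 with vrs4.k, vrs1 and int-c.5), 4.33 (vrs4.k and int-c.5) and 2.83 (vrs1 and int-c.5) at W3.5, and 14.5, 13, 3.33, 3.33 and 2.83 at W5.5. Averaged over both stages, calls were 643, 466, 150 and 104 in int-a.1, vrs4.k, vrs1 and int-c.5, and averaged over 5 lines, 5011 between stages. With the first principal component as covariate, 29.6% of vrs1 W3.5 calls lay on the locus chromosome, and the vrs4.k average had 756 calls. Without the 4 libraries apart from their stage, int-a.1 at W5.5 had 325 calls and its average 1006, and int-a.1 and int-c.5 shared 12 at W3.5 and 4 at W5.5, and vrs1 and int-c.5 3 at W5.5. The densest window of vrs4.k at W5.5 had permutation p = 0.012 with 25 transcripts, at 58.78 of chromosome 2, which is not the locus chromosome, and 0.043 with 100 transcripts, at 46.03 to 46.88 of chromosome 3. A mean-variance trend put 40% of int-c.5 W5.5 calls on the locus chromosome. With an estimated correlation 0 list tests passed, and with the stricter filter 67.

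Leaving out 1 library at a time gave 125 to 303 calls in int-a.1 at W3.5 (303 without Bowman replicate 4, 126 without Bowman replicate 2, 125 without int-a.1 replicate 3), 138 to 342 in vrs4.k at W3.5 (342 without Bowman replicate 4), 24 to 50 in int-c.5 at W3.5 (50 without Bowman replicate 1) and 18 to 34 in int-c.5 at W5.5 (18 without its replicate 1, 20 without its replicate 3). The share on the locus chromosome in vrs1 at W3.5 was 25.8% to 33.3%, and it passed without Bowman replicate 1 (32.4%), vrs1 replicate 1 (32.4%) or vrs1 replicate 3 (33.3%). In int-c.5 that share, on few calls, was 0% to 7.14% at W3.5 (7.14% without Bowman replicate 1) and 0% to 40% at W5.5 (0% without Bowman replicate 2 or 4 or int-c.5 replicate 1 or 3, 40% without Bowman replicate 3). Between stages the range was 0 to 415 in Bowman (415 without W3.5 replicate 4, 43 without W3.5 replicate 3, 177 without W5.5 replicate 1), 0 to 14 in int-a.1 (14 without W3.5 replicate 1, 0 without W3.5 replicate 2 or W5.5 replicate 1, 6 without W5.5 replicate 3) and 0 to 5 in int-c.5 (5 without W5.5 replicate 1, 1 without W3.5 replicate 1), and 0 to 2 for the interaction of int-a.1 (2 without int-a.1 W3.5 replicate 1). Shared calls at W3.5 ranged from 17 to 67 (int-a.1 and vrs4.k; 67 without Bowman replicate 4, 18 without Bowman replicate 3, 19 and 17 without int-a.1 replicates 2 and 3), 17 to 45 (int-a.1 and vrs1; 45 without Bowman replicate 4, 17 without Bowman replicate 3) and 4 to 8 (vrs1 and int-c.5; 4 without Bowman replicate 2 or vrs1 replicate 3). At W5.5 they ranged from 15 to 42 (int-a.1 and vrs4.k; 15 without int-a.1 replicate 1, 24 without Bowman replicate 3), 12 to 36 (int-a.1 and vrs1; 12 without int-a.1 replicate 1), 4 to 9 (int-a.1 and int-c.5; 4 without Bowman replicate 4 or any 1 int-c.5 replicate, 5 without Bowman replicate 3 or int-a.1 replicate 2 or 3), 3 to 8 (vrs4.k and int-c.5; 3 without int-c.5 replicate 3, 4 without its replicate 1 or Bowman replicate 4) and 3 to 6 (vrs1 and int-c.5; 3 without vrs1 replicate 2 or int-c.5 replicate 3). The averages over both stages had 415 to 806 calls in int-a.1 (415 without int-a.1 W3.5 replicate 3), 284 to 811 in vrs4.k (811 without Bowman W3.5 replicate 4, 308 without vrs4.k W3.5 replicate 1, 284 without vrs4.k W5.5 replicate 1) and 53 to 127 in int-c.5 (53 without int-c.5 W3.5 replicate 3, 68 without int-c.5 W5.5 replicate 3). The average over 5 lines had 2731 to 7744 (vrs4.k W3.5 replicates 3 and 2; 2982 without int-a.1 W3.5 replicate 2, 2930 without vrs1 W5.5 replicate 3, 3094 without vrs4.k W5.5 replicate 2, 3021 without int-c.5 W5.5 replicate 2). List tests passed in 60 to 82 cases.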

Other observations

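No test was chosen for this part, and the levels of single libraries and the choice of transcripts outside the naming rule followed after the values were seen. Disease resistance transcripts of the NB-ARC class were among the called defence transcripts in vrs4.k. MLOC_4344.2 (chromosome 7, 1.912) fell to 3.37 ± 0.833 TPM (SD, n = 3) from 10.9 ± 0.403 (n = 4) at W3.5 and to 4.2 ± 1.28 from 14.1 ± 0.673 at W5.5 (log2 folds -1.47 and -1.57). MLOC_64709.2 (chromosome 5, 166.3) fell to 0.267 ± 0.0577 from 3.9 ± 0.424 TPM and to 0.3 ± 0.265 from 5.55 ± 0.507 (-1.95 and -2.35). The thaumatin-like AK369434 (chromosome 3, 96.74), of a pathogenesis-related family, fell to 9.7 ± 0.608 from 17.2 ± 2.72 TPM at W3.5 (-0.75), a call lost with only the compared groups.

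In the average of 5 lines between stages, the linker histone transcript MLOC_66584.1 (chromosome 5, 125.8) rose to 220 ± 26.8 TPM at W5.5 from 164 ± 29.7 at W3.5 (n = 16 each; 0.43), and the histone H3 transcript AK355128 (chromosome 7, 13.88) to 497 ± 71.4 from 390 ± 52.3 (0.35). The LOB-domain transcript MLOC_35680.1, an LBD41 match, fell to 0.384 ± 0.638 from 2.12 ± 1.38 TPM (-1.11), and the AP2-domain MLOC_55323.1 (chromosome 7, 47.73) to 1.2 ± 0.877 from 4.34 ± 2.23 (-1.25).

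The low-confidence transcript MLOC_29531.1 (chromosome 5, 125.8) was called lower in int-a.1, vrs4.k and vrs1 at W5.5, at 1.3 ± 0.520, 1.3 ± 0.889 and 0.8 ± 0.265 TPM against 20.9 ± 4.63 in Bowman, and was at 19.2 ± 4.02 TPM in int-c.5. The summed histidine kinase level of single int-a.1 libraries was 166.7, 265.2 and 264.3 TPM at W3.5 and 124.5, 327.8 and 324.5 TPM at W5.5, against 53 to 112 in the 12 vrs1 and vrs4.k libraries and 407.4 to 550.1 in the 8 Bowman libraries; whether plants of the int-a.1 stock were genetically uniform is not given in the sources used here.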
